A study of Solanum lycopersicum with 30 samples.

How the data were processed

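RNA sequencing was carried out on MicroTom, a dwarf tomato cultivar, watered with tap water or with tap water passed through a static magnetic device. Per the labels' protocols the field was 260 mT and the flow at most 4800 l per h. Plants were sampled at 5 stages: 3-week-old seedlings, 6-week-old vegetative plants, blooming, the start of berry formation and full ripening. Whole seedlings were taken first, leaf with stem afterwards, and flowers were added only at blooming. The labels give 3 biological replicates per group, 10 groups and 30 libraries. The labels' extraction text speaks of wheat and of ultrasound and names both oligo(dT) capture and ribosomal RNA removal, so the enrichment used for these libraries is uncertain.

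The deposited values are a signal per transcript model in 35076 probes and 10 columns, 1 column per group. Multiplied by 3, 100% of the values were whole numbers at a tolerance of 0.001, so each deposited signal column holds the mean of raw counts over the 3 libraries of its group, without depth normalization. The read sums over 3 libraries were recovered in this way, and no value per library was available for analysis. Per the submitters' processing notes, FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10b, edgeR, DESeq2 and R 4.2.3 were used, with no role stated. The genome build and the read counter are not given in the sources used here, and probe coordinates are therefore not printed. Of the probes, 987 carry the ENSRNA prefix that Ensembl gives to non-coding RNA annotations and 34089 carry tomato gene numbers.

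Read sums were scaled by TMM in edgeR 4.0.16 to CPM, the depth-scaled read count of edgeR. For each stage, and for each step between neighbouring stages in tap-water plants, genes with a mean of at least 5 CPM over both columns were compared as log2 of (CPM + 1), and genes at least 2-fold apart were counted. Such folds on the log2(CPM + 1) scale understate the change of low genes. These comparisons have no replicate check and carry no p-value. Ratios of named genes are ratios of CPM with exact Clopper-Pearson 95% intervals on the read sums. The intervals cover counting error only, not the spread between plants. The number of genes at least 2-fold apart expected from counting alone came from 20 binomial simulations per comparison. Reads were also simulated for 18035 genes of the vegetative comparison, with a small part of the genes changed. Those changed by a log2 of 1 were estimated at a median of 0.98. Of the intervals of the changed genes, 97.0% held the true value. These reads had counting error alone, as the intervals assume, so coverage near 95% was built in.

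The design fixed before the data were examined asked for edgeR within each stage with 3 libraries against 3. It could not be fitted, because only group means were at hand, and neither could the treatment by stage interaction, which leaves no residual degrees of freedom. The single replicated test of treatment took the 5 stages as blocks in limma 3.58.1 (trend = TRUE) on log2(TMM CPM + 1), with R 4.3.3, filterByExpr and Benjamini-Hochberg adjustment at 0.05 over 21174 genes. Tests of the development steps used the same kind of model with treatment as a block, so that each stage had 2 columns. This second model was chosen after seeing the data. On simulated counts for the common effect, run on 21156 genes with edgeR's common dispersion, limma recovered 95% of 100 genes changed by a log2 of 1 and 100% of those changed by 2, with 8 false calls. That simulation gave every stage the same treatment effect and every gene the same dispersion (0.029). Genes that vary more would be recovered less often, so its recovery is not the power of the real test. For the step from seedling to vegetative, simulated with the same dispersion on 22830 genes, limma recovered 48% at a log2 of 1 and 96.0% at 2, with 12 false calls. edgeR quasi-likelihood and DESeq2 1.42.0 on the recovered reads, other size factors, a pseudocount of 0.1, no filter, and the removal of each stage were run as alternatives.

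The deposited table pairs no gene number with a name, and the gene name table of assembly SLM_r2.1 holds none of these numbers. Only 11 of the 34 gene lists fixed in advance contained gene numbers. A list of 360 tomato gene numbers in 30 lists was therefore written from general knowledge, 50 of them fixed in advance and 310 added after the structure of the table had been seen, before the change of any listed gene was computed. A RefSeq symbol was attached only where its gene lay on the same chromosome and in the same place among neighbouring listed genes. Its shift from 4 neighbours had to be within 100 kb with a length ratio of 0.5 to 2, or within 2 Mb with a ratio of 0.9 to 1.1. The wider allowance was added after a first pass. By then the genome-wide numbers of changed genes and the most counted genes had been seen, but no fold of a listed gene. It gave 256 named loci, of which 217 overlapped no other probe and are used by name below. The gene lists were not limited to these loci. They drew on all 319 listed numbers present in the table. Some of these failed the name check or overlapped another probe, so the identity of some list members is unchecked. Named genes were the up to 12 higher and 12 lower with the largest fold among those at 1.5-fold or more and 5 CPM. The rule fixed in advance needed p-values and could not be used.

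Lists were tested on the common effect with limma's camera at a preset correlation of 0.01. Within a stage, a list's median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The random lists drew genes independently of each other, so correlation among list members was not allowed for. The position describes these columns and is not a test. Probes overlapping on opposite strands made up 15.8% of all probes. Among 1188 pairs sharing 80% of the shorter probe, levels correlated across pairs with Spearman's rho of 0.49, against 0.09 for 14841 neighbours without overlap. Whether the counting used strand is not given in the sources used here, so overlapping probes were not named. Closely related gene copies, such as those of photosynthesis genes, can share reads and are uncertain.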

Results

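Transcript levels were compared between tomato plants watered with magnetized water and plants watered with tap water at 5 stages of development. The labels ask how such watering affects the transcriptome over development. Each of the 10 groups held 3 libraries, taken to be pooled in the data into 1 mean per group. Summed over 3 libraries, the groups held between 5771783 reads (tap-water seedlings) and 11939797 reads (magnetized water, berry formation). Probes with a read numbered from 22782 in tap-water seedlings to 25085 at blooming with magnetized water. The 10 most counted genes took between 0.52% (tap water, vegetative) and 0.73% (magnetized water, seedlings) of the reads of a group. No comparison within a stage has a replicate check, and the words higher and lower there describe the group means alone.

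In seedlings, genes of photosynthesis and carotenoid synthesis were higher with magnetized water, and ethylene genes were lower. SP5G (Solyc05g053850), a repressor of flowering, was 5.48-fold higher (95% counting interval 3.48 to 9.03), from 3.86 to 21.1 CPM. The ethylene synthesis gene ACS2 (Solyc01g095080) had 16.6 CPM with tap water and 1 read with magnetized water, a ratio of 112 with an interval of 19.6 to 4463. The chitinase gene CHI3 was 5.80-fold lower (4.65 to 7.29), and the sucrose synthase gene sus3 was 4.54-fold lower (3.94 to 5.25). Across 17410 genes, 184 were at least 2-fold higher and 242 at least 2-fold lower, where counting alone would give 0.75.

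All 15 measured light harvesting and photosystem genes had a higher mean in treated seedlings, with a median log2 fold of 0.32, although 1 reached 1.5-fold (CAB6A, a chlorophyll-binding protein, from 86.4 to 143 CPM). The median lay at percentile 100 of the matched random lists. Such positions were common: 14 of 26 lists lay in the outer 5% in seedlings and 7 of 27 in vegetative plants. At blooming 5 of 28 did so, at berry formation 13 of 27 and at ripening 13 of 26. Independently drawn genes would give 1.3 to 1.4. Members of some lists varied together, with an estimated correlation of 0.94 for light harvesting genes, against 0.03 for jasmonate genes. A list whose members vary together can reach an outer position without a treatment effect. The 4 Calvin cycle genes had a median of 0.52, and ca2, a carbonic anhydrase gene listed with them that has no step in the cycle itself, had 266 and 542 CPM. All 13 carotenoid synthesis genes were above the tap-water level, with a median of 0.47 and 3 of them at 1.5-fold. Steroidal glycoalkaloid genes, which make the bitter defence compounds of tomato, had a median of 0.32, and GAME6 was 1.88-fold higher (1.57 to 2.25). Of 11 photoreceptor genes, 3 were at least 1.5-fold higher and none was as much lower. The blue-light receptor gene Cry1b was 1.57-fold higher (1.41 to 1.75), while CRY2 had 99.5 CPM with tap water and 84.0 CPM with magnetized water. At the later stages, the only photoreceptor gene of 11 at 1.5-fold or more was PHYB2 at blooming, with 28.8 and 45.5 CPM. Among 20 ethylene genes, 17 were below the tap-water level, with a median of -0.27 at percentile 0. The ethylene receptor gene ETR4 was 2.44-fold lower (2.11 to 2.83) and the response factor gene PTI5 was 2.00-fold lower (1.38 to 2.94). ACO1, which makes the last step of ethylene synthesis, went the other way and was 2.06-fold higher (1.80 to 2.36). The auxin-conjugating gene GH3.2 was 5.95-fold lower (3.51 to 10.7). The gibberellin-inactivating genes GA2ox4 and GA2ox5 were 2.96-fold and 2.13-fold lower. Floral and fruit genes were low at this stage: DEF had 2.80 and 8.04 CPM, and TAGL1 had 3.50 and 8.78 CPM.

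**Figure D1:**
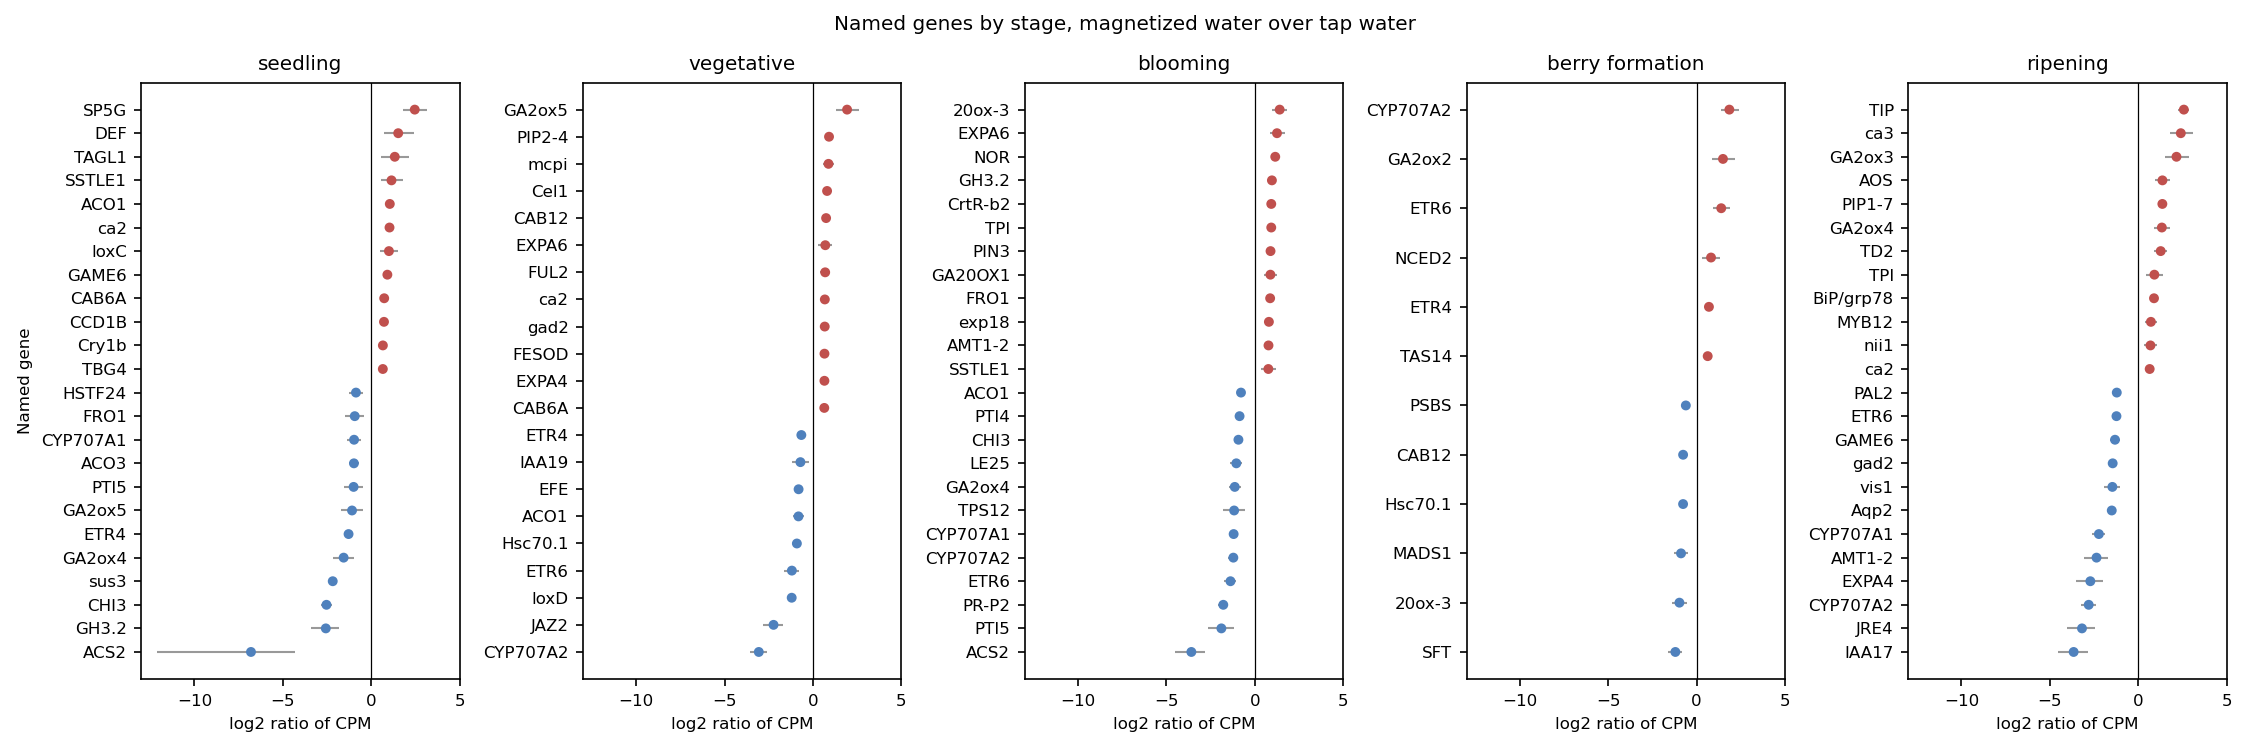
Ratio of CPM, magnetized water over tap water, on a log2 axis, for the named genes of each stage; points are ratios of group means and grey lines are exact 95% counting intervals, with no replicate error. The ratio of ACS2 in seedlings rests on 1 read in the treated group.

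In vegetative plants, 94 of 17899 genes were at least 2-fold higher with magnetized water and 324 were at least 2-fold lower. The abscisic acid hydroxylase gene CYP707A2 was 8.39-fold lower, from 37.2 to 4.44 CPM, with a lower counting bound of 6.04. The jasmonate repressor gene JAZ2 was 4.71-fold lower (3.19 to 7.16) and the lipoxygenase gene loxD 2.31-fold lower (2.03 to 2.63). The 11 jasmonate genes as a list did not lean that way, with 6 higher, 5 lower and a median log2 fold of 0.06. All 8 pathogenesis-related genes were below the tap-water level, with a median log2 fold of -0.41 at percentile 0.03, and 2 of them were 1.5-fold lower. The ethylene genes EFE and ETR6 were 1.76-fold and 2.29-fold lower.

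All 15 light harvesting and photosystem genes were above the tap-water level at the vegetative stage, with a median of 0.42. CAB12 went from 120 to 200 CPM. The treated group held 0.74 times the reads of its control, and the 2% of genes with most reads per base had a median log2 fold of 0.29, so the same direction was seen in read-dense genes as a class. Cell wall genes had a median of 0.36, with 13 of 15 higher, among them the endoglucanase gene Cel1 (1.73-fold, 1.57 to 1.91) and the expansin gene EXPA4 (1.56-fold, 1.39 to 1.75). The aquaporin gene PIP2-4, a water channel of the plasma membrane, was 1.87-fold higher (1.65 to 2.12) and 8 of 10 aquaporins were above the tap-water level. GA2ox5 was 3.79-fold higher (2.47 to 5.97), opposite to seedlings. The proteinase inhibitor gene mcpi was 1.83-fold higher, from 14.4 to 26.4 CPM. Of 45 probes with non-coding RNA identifiers and a mean of at least 5 CPM over all 10 columns, 35 were at least 2-fold lower, and these probes had a median log2 fold of -1.32. Without any probe of this kind, and with the minimum set on the vegetative columns, 292 of 17857 genes were at least 2-fold lower.

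At blooming, 321 of 19006 genes were at least 2-fold higher with magnetized water and 355 were at least 2-fold lower. Of the same 45 non-coding RNA probes, 9 were at least 2-fold lower, and their median log2 fold was -0.79. Pathogenesis-related and ethylene genes were lower. All 9 pathogenesis-related genes were below the tap-water level, with a median log2 fold of -0.91 at percentile 0, and 5 of them were at least 1.5-fold lower. PR-P2 was 3.44-fold lower (2.84 to 4.19) and CHI3 had 107 CPM against 56.2 CPM (interval of the ratio 1.71 to 2.10). ACS2 was lower, from 15.9 to 1.32 CPM, with an interval of the ratio of 6.95 to 22.5.

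Of 22 ethylene genes, 18 were below the tap-water level, with a median of -0.33 and 5 at 1.5-fold or more. PTI5 was 3.71-fold lower, from 8.07 to 2.18 CPM, ETR6 2.59-fold (2.06 to 3.28) and ACO1 1.72-fold (1.58 to 1.87). Both abscisic acid hydroxylase genes were lower, CYP707A1 by 2.29-fold (2.04 to 2.58) and CYP707A2 by 2.32-fold (1.91 to 2.82). Auxin genes had a median of 0.16, with GH3.2 1.96-fold higher (1.78 to 2.16) and the auxin transporter gene PIN3 1.85-fold higher (1.62 to 2.12). The gibberellin 20-oxidase genes 20ox-3 and GA20OX1 were 2.65-fold and 1.84-fold higher, and the inactivating gene GA2ox4 was 2.19-fold lower. NOR, a regulator of fruit ripening, was 2.23-fold higher (1.95 to 2.55), and CrtR-b2, a carotene hydroxylase of flowers, was 1.91-fold higher (1.74 to 2.09). The floral organ gene TPI went from 40.1 to 76.5 CPM, and 10 of 11 floral organ genes were above the tap-water level with a median of 0.19. The 6 pollen and anther genes had a median of -0.18, at percentile 13.5, with LAT52 at 395 and 371 CPM. All 5 wound-induced defence genes were above the tap-water level, with a median of 0.44.

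At the start of berry formation the groups lay closest together. Of 17587 genes, 75 were at least 2-fold higher with magnetized water and 115 were at least 2-fold lower, and 95.7% lay within 1.5-fold. CYP707A2 was 3.62-fold higher (2.57 to 5.20), and the ethylene receptor genes ETR6 and ETR4 were 2.63-fold (1.91 to 3.68) and 1.63-fold (1.43 to 1.85) higher. SFT, the tomato florigen gene, was 2.29-fold lower (1.76 to 3.00), from 16.6 to 7.22 CPM. The dehydrin gene TAS14, which responds to water deficit, was 1.55-fold higher (1.39 to 1.73).

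All 15 light harvesting and photosystem genes were below the tap-water level at berry formation, with a median of -0.41, and 2 were at least 1.5-fold lower. CAB12 was 1.69-fold lower (1.47 to 1.94), and PSBS, the sensor of excess light in photosystem II, was 1.52-fold lower (1.38 to 1.67). The treated group was 1.29 times as deep as its control, and the 2% most read-dense genes had a median of -0.19. The 6 housekeeping genes also had a median of -0.29, at percentile 0.1. Reactive oxygen scavenging genes had a median of -0.18, with 14 of 15 below the tap-water level and none at 1.5-fold. Of the same 45 non-coding RNA probes, 32 were at least 2-fold lower. Without any probe of this kind, and with the minimum set on the berry formation columns, 89 of 17551 genes were at least 2-fold lower.

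**Figure D2:**
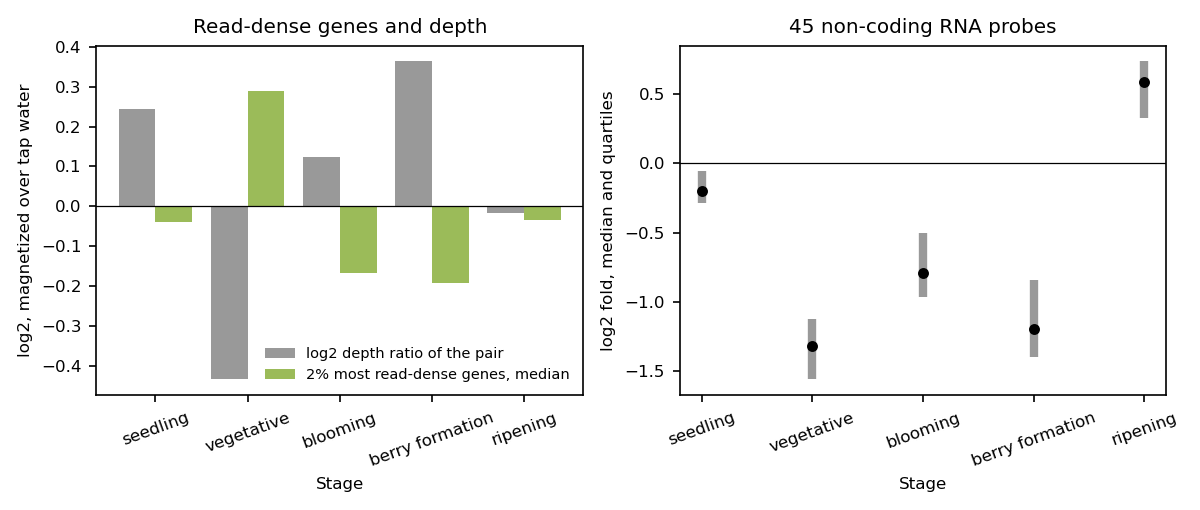
Left, log2 ratio of reads (magnetized over tap water) and median log2 fold of the 2% most read-dense genes by stage. Right, median and quartiles of the log2 fold of 45 non-coding RNA probes; the median is -1.32 in vegetative plants and 0.59 at ripening.

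**Figure D3:**
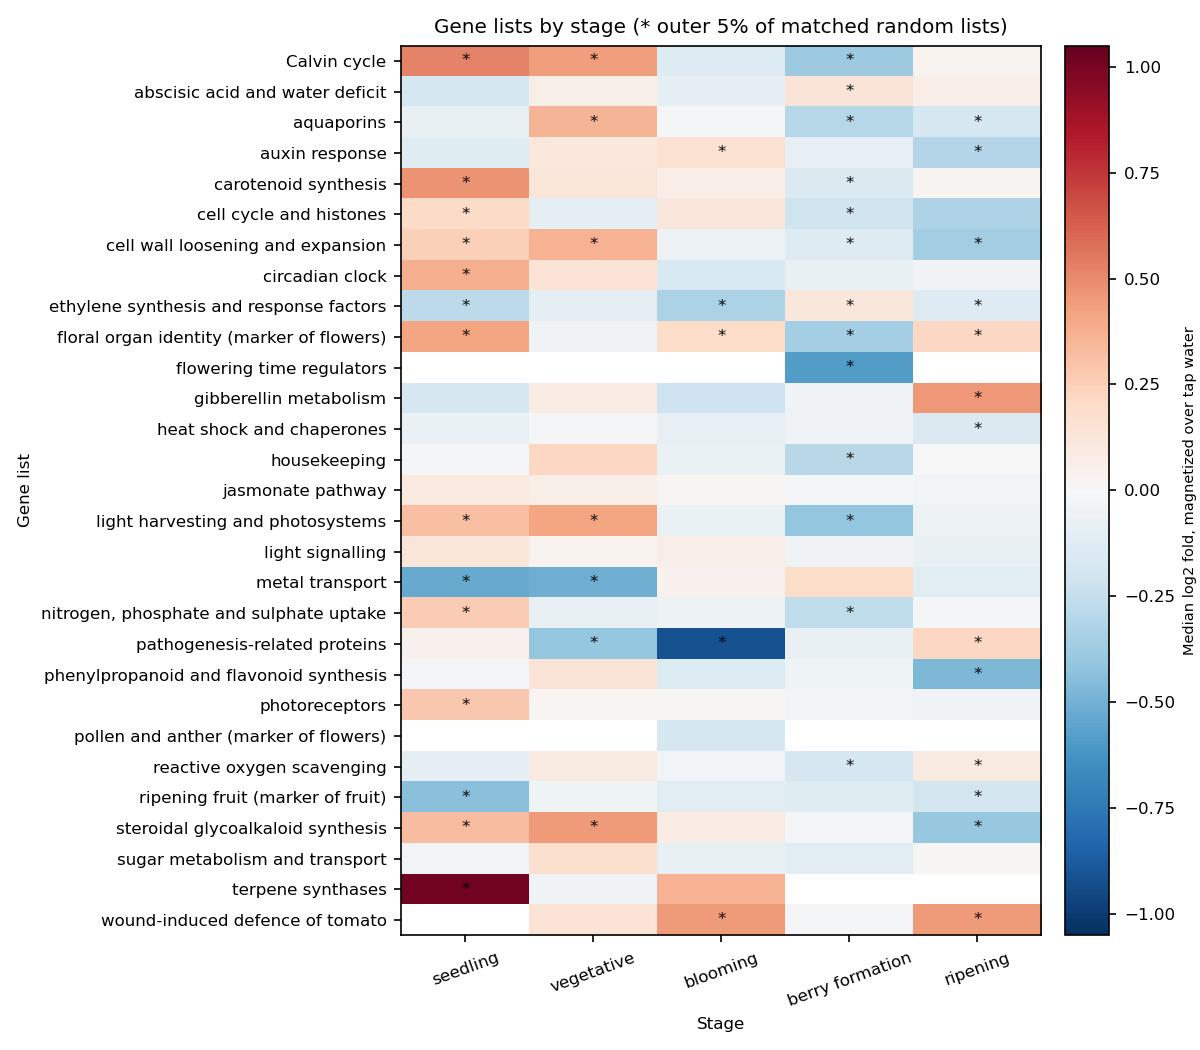
Median log2 fold of each gene list, magnetized water over tap water, by stage; an asterisk marks a median in the outer 5% of 10000 random lists matched on mean expression, and white cells held fewer than 3 genes or had a median close to 0. Light harvesting genes are above 0 in vegetative plants (0.42) and below 0 at berry formation (-0.41).

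At ripening, where leaf and stem were sampled, 421 of 17233 genes were at least 2-fold lower with magnetized water and 105 were at least 2-fold higher. Auxin, cell wall, glycoalkaloid and phenylpropanoid genes were lower. The auxin response gene IAA17 was 12.6-fold lower (7.31 to 23.5), from 14.8 to 1.18 CPM. JRE4, the regulator of glycoalkaloid synthesis, was 9.08-fold lower (5.40 to 16.3), and the synthesis gene GAME6 was 2.49-fold lower (2.06 to 3.01). The aquaporin gene TIP was 5.97-fold higher (4.84 to 7.43), from 8.68 to 51.8 CPM.

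Of 15 auxin genes at ripening, 14 were below the tap-water level, with a median of -0.30. Cell wall genes had a median of -0.37, with 6 of 14 at least 1.5-fold lower, including EXPA4 (6.54-fold, 3.91 to 11.6). Of 9 glycoalkaloid genes, 8 were below the tap-water level, with a median of -0.40. Phenylpropanoid genes had a median of -0.47, with 11 of 14 below the tap-water level, 2 at least 1.5-fold lower and 1 at least 1.5-fold higher. PAL2, which starts the pathway, was 2.32-fold lower (2.06 to 2.63), and MYB12, a regulator of flavonoid synthesis, was 1.64-fold higher (1.30 to 2.08). CYP707A1 and CYP707A2 were 4.68-fold (3.63 to 6.10) and 6.97-fold (5.22 to 9.49) lower. The ammonium transporter gene AMT1-2 was 5.13-fold lower (3.30 to 8.32). Aquaporins parted ways: PIP1-7 was 2.57-fold higher, from 36.8 to 94.5 CPM, and Aqp2 was 2.83-fold lower (2.47 to 3.25). The jasmonate synthesis gene AOS was 2.58-fold higher (1.95 to 3.43), the defence gene TD2 was 2.41-fold higher (1.87 to 3.13), and the chaperone gene BiP/grp78 was 1.85-fold higher (1.73 to 1.99). Of 17 heat shock genes, 5 were at least 1.5-fold lower, with a median of -0.15. Pathogenesis-related genes had a median of 0.22, opposite in sign to blooming, a difference that was not tested. PG2, the polygalacturonase of ripe fruit, had 0.08 CPM with tap water and 0 reads with magnetized water.

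Taking the 5 stages as blocks, limma called no gene as different between the waters over development. It called 0 of 21174 genes, with 677 at an unadjusted p under 0.05, fewer than the share of 0.05 that chance would give. edgeR's quasi-likelihood test on the recovered reads called 0, with 570 at an unadjusted p under 0.05, also below that share. DESeq2 called 6, all lower. With 1 column per group, any difference of the treatment effect between stages counts as error in these tests. Changes limited to some stages can therefore be missed. Among named genes the smallest p was that of the chitinase gene CHI9, with a log2 fold of -0.40 (SE 0.08) and a limma adjusted p of 1.00. Its mean was lower in 5 of 5 stages. The wound-induced gene TD2 had a log2 fold of 0.80 (SE 0.24) and was higher in 5 of 5 stages, with a limma adjusted p of 1.00.

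Over the stages, camera called 5 of 28 gene lists at a preset correlation and 0 with an estimated one. Ethylene genes were lower (23 genes, median log2 fold -0.18, adjusted p = 4.4e-05, and 0.47 with an estimated correlation), as were pathogenesis-related genes (9 genes, -0.33, adjusted p = 0.00024) and ripening-fruit genes (9 genes, -0.25, adjusted p = 0.003). For these last lists, too, the adjusted p was 0.47 with an estimated correlation. The ripening-fruit list had an estimated correlation of -0.06, below the preset one. Its unadjusted camera p still went from 0.00054 to 0.023, so correlation among its members was not what removed its call. Wound-induced defence genes were higher (4 genes, 0.59, adjusted p = 0.00027), as were carotenoid genes (14 genes, 0.09, adjusted p = 0.0028). With an estimated correlation their adjusted p was 0.47 and 0.84. Of the 5 lists, the ripening-fruit list alone had a median of the same sign at all stages. At berry formation the ethylene list had a median of 0.12, with 14 of 20 genes higher, and the carotenoid list had a median of -0.15, with 11 of 14 lower. The ethylene list had medians of -0.10 at the vegetative stage and -0.14 at ripening. The pathogenesis-related list had medians of 0.05 in seedlings and 0.22 at ripening, and the wound-induced list had a median of -0.01 at berry formation. No member of any list was called over all genes. Adjusted over the list alone, 1 of the pathogenesis-related, 1 of the wound-induced, 1 of the metal transport and 2 of the ripening-fruit genes were called. The interaction of treatment and stage was not tested. Between stages, correlations across 18844 genes of the log2 folds lay between -0.21 (vegetative with ripening) and 0.09 (berry formation with ripening), and genes are not independent replicates.

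**Figure D4:**
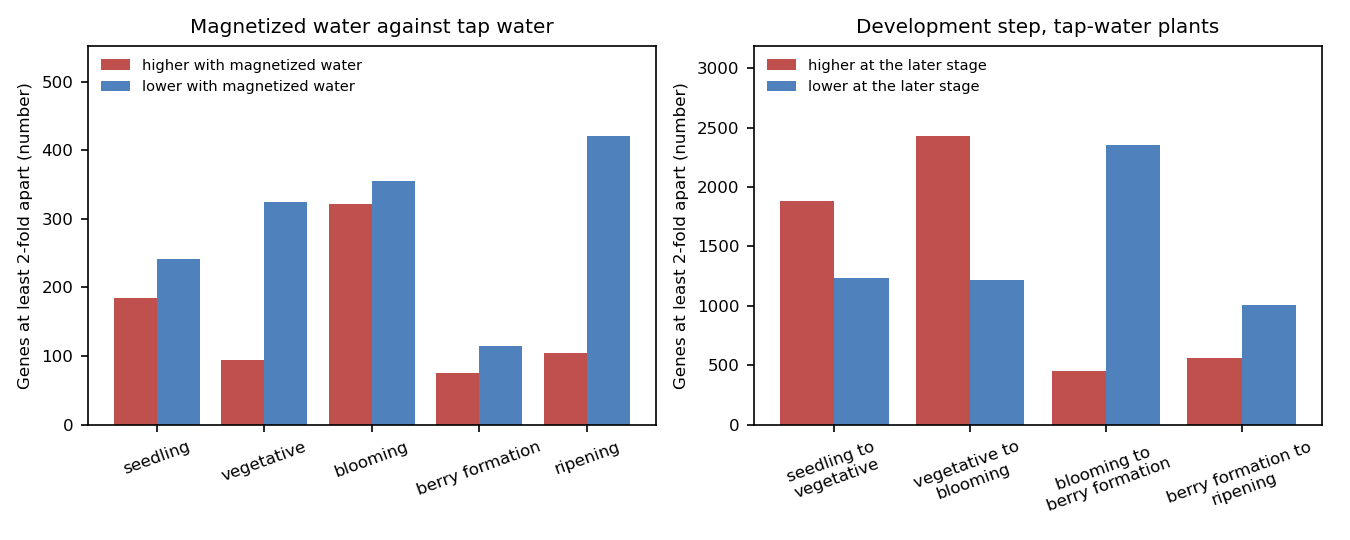
Number of genes at least 2-fold apart (means of at least 5 CPM) for magnetized water against tap water at each stage (left) and between neighbouring stages of tap-water plants (right); the 2 vertical scales differ. Treatment gave 190 to 676 such genes per stage and the steps between stages 1574 to 3648.

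More genes were at least 2-fold apart between neighbouring stages than between the waters. The first 3 steps also changed the organs sampled, so stage and organ cannot be told apart there. In tap-water plants 3120 genes were at least 2-fold apart between seedling and vegetative stage, 3648 between vegetative and blooming, 2805 between blooming and berry formation, and 1574 between berry formation and ripening. Among genes with a mean of 5 CPM over both waters, 3130, 3620, 2831 and 1521 were at least 2-fold apart in tap-water plants. Of these, 76.6%, 78.1%, 79.9% and 70.7% were also at least 2-fold apart, in the same direction, in plants given magnetized water. With both waters as columns of a stage, limma called 9412, 7901, 6315 and 2504 genes for the 4 steps.

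From seedling to vegetative stage, the flavonoid genes CHS1 and DFR rose, CHS1 by a log2 of 3.82 (SE 0.17, limma adjusted p = 7.9e-05) and DFR by 3.53 (SE 0.19, adjusted p = 0.00012). The endoglucanase gene Cel1 rose by 5.06 (SE 0.34), TAS14 rose by 4.13 (SE 0.21), and the ammonium transporter gene AMT1-1 fell by 2.16 (SE 0.16). From vegetative to blooming, LAT52, a pollen gene, rose by 8.03 (SE 0.32, limma adjusted p = 1.4e-06), the floral organ gene DEF by 5.62 (SE 0.50) and NOR by 5.63 (SE 0.41). Over that step in tap-water plants all 8 measured cell cycle genes were at least 1.5-fold lower. From blooming to berry formation, when flowers were no longer sampled, LAT52 fell by 5.13 (SE 0.32) and the pollen kinase gene PRK1 fell by 7.03 (SE 0.26), while SFT rose by 1.71 (SE 0.49, limma adjusted p = 0.037). From berry formation to ripening, the gibberellin synthesis gene GA20OX1 fell by 3.07 (SE 0.34, limma adjusted p = 0.006), the expansin gene EXP2 fell by 2.64 (SE 0.20) and the glycoalkaloid gene GAME17 fell by 2.22 (SE 0.12). PR-P2 rose by 1.88 (SE 0.47, adjusted p = 0.044).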

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

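The 20 CPM minimum, total-count scaling, the removal of non-coding RNA probes, the removal of abundance trends, the edgeR test, the tests of development steps and the list tests without a stage were chosen after seeing the data. No paired analysis was possible because the columns are group means and carry no replicate numbers. For the same reason the fits without 1 library, the fit over all libraries, the fold limit beside an adjusted p, DESeq2 within a stage and the interaction were not run. Of 90 values over 15 comparisons, 72 lay within 1.5 times the main count and 18 did not. With no filter on low values, genes at least 2-fold apart numbered 847 in seedlings, 806 in vegetative plants, 1071 at blooming, 416 at berry formation and 1078 at ripening, and 2601 for the step from berry formation to ripening. With a minimum of 20 CPM they numbered 175, 117, 302, 46 and 145, and 1704, 2064, 1594 and 669 for the 4 steps. At blooming the larger part changed sides, with 171 higher and 131 lower, against 321 and 355 in the main count. These settings test more or fewer genes by construction. DESeq2 called 6 genes for the common effect where limma called 0, and the cause was not tested. An estimated correlation left 0 gene lists and leaving out the vegetative stage gave 9, against 5. Total-count scaling moved the median gene by -0.20 (log2) for the step into blooming and by 0.17 for the step out of it. The share of higher genes went from 66.6% to 54.7% and from 16.1% to 26.6%. The 105 named treatment ratios kept their sign under other size factors and a pseudocount of 0.1, but this was assured beforehand. A pseudocount cannot turn a sign. The other size factors moved the median gene by 0.02 (log2) at ripening, their largest shift at any stage, and named genes were at least 1.5-fold apart. A sum of 3 reads was worth 0.52 CPM in tap-water seedlings, so genes near that level were not resolved.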

Other observations

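All tests in this part were chosen after the results were seen. With the treatment labels swapped within stages in every possible way, 16 splits can be made, too few for a share under 0.05. The real split called 0 genes and the highest of the others 0, so that 16 of 16 gave as many. Every split meets a count of 0, so this comparison decides nothing. Genes at an unadjusted limma p under 0.05 numbered 677 in the real split and from 506 to 1876 in the others. Most of the others had more than the real split. For gene lists the real split called 5 and the highest of the others 8, and 10 of the 16 splits gave as many. The number of lists called therefore did not stand out from swapped labels. The ethylene, pathogenesis-related and wound-induced lists were each also called in some swapped splits.

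Most genes at least 2-fold apart at some stage were so at a single stage. Of 18844 genes, 2039 were at least 2-fold apart at some stage, 1587 of them at a single stage, and 56 in the same direction at 3 or more stages. A share of 4.39% had 1 sign at all 5 stages, where 6.25% would arise by chance. Genes at least 2-fold apart at both stages of a pair did not share a direction in every pair. The direction was the same for 85 of 104 between vegetative plants and blooming and for 76 of 96 between vegetative plants and berry formation. Independent stages would give 8.6 and 3.9. The direction was the same for the smaller part in 3 of the 10 pairs, among them 15 of 42 between seedlings and berry formation. The others were 32 of 82 between vegetative plants and ripening, and 28 of 66 between berry formation and ripening. Independent stages would give 3.4, 15.5 and 6.4 in these 3 pairs. All 10 pairs lay above the number from independent stages, and the source of this excess was not tested. CYP707A2, the abscisic acid hydroxylase gene, was lower with magnetized water at the other 4 stages and higher at berry formation. Its levels at berry formation were 4.32 and 15.6 CPM.

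Probes with non-coding RNA identifiers with a mean of at least 5 CPM over all columns made up 31 of the 71 genes at least 2-fold lower at both the vegetative stage and berry formation. Over the 10 columns these 45 probes had a mean pairwise correlation of 0.78, above the highest of 1000 matched random lists, 0.15. Their median was -0.20 in seedlings, -1.32 at the vegetative stage, -0.79 at blooming and -1.20 at berry formation. At ripening it was 0.59, with quartiles of 0.33 and 0.74. A treatment effect of one direction at every stage cannot by itself give both signs. Such an effect beside another difference between columns is not excluded, since each group is a single column. The quartiles are over probes that vary together, not over replicates. A varying share of structural RNA carried into the libraries is a candidate explanation. It cannot be told apart from a stage-specific effect of the water, because each group is a single column.

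The most read-dense genes moved against the depth of the pair at 4 of 5 stages. The median of these genes was 0.29 at the vegetative stage, where the log2 depth ratio was -0.43, and -0.19 at berry formation, where it was 0.36. Seedlings had -0.04 with a ratio of 0.24, blooming -0.17 with 0.12, and ripening -0.03 with -0.02. A candidate explanation is that counts of read-dense genes level off with depth, as when duplicate reads are removed, which predicts opposite signs and met them at 4 stages. It cannot be told apart from an effect of the water on these genes, since depth and water differ together in each pair. Counts that level off would also make the folds of read-dense genes too small. In seedlings, light harvesting genes had a median of 0.32, against the direction that depth would give.

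A hypothesis is that treated plants were further along in development at berry formation. The berry formation difference correlated across 18844 genes with the change from vegetative plants to ripening, at r = 0.26 in tap-water plants and 0.26 in treated plants, which share no library with it. The relation did not rest on the 10% most read-dense genes, without which r was 0.26, or on the non-coding RNA probes, without which r was 0.25. A depth effect is not excluded, since the berry formation fold followed read density over all genes (Spearman's rho -0.23). A difference in carried-over RNA is not excluded either, since only 45 of the 18844 genes were such probes. The other stages gave r of -0.01 (seedling), -0.16 (vegetative), -0.26 (blooming) and 0.21 (ripening) on axes of leaf and stem from other stages. Axes that start at whole seedlings of tap-water plants gave 0.31 for berry formation, 0.13 (vegetative), -0.16 (blooming) and -0.09 (ripening). The signs of the vegetative and ripening values therefore turned with the axis. Values of like size in both directions at other stages, with no replicate, leave the hypothesis open. Whether age, depth, carried-over RNA or chance gave the relation cannot be told apart.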
